A study of Mus musculus with 76 samples.

How the data were processed

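Lung RNA from single female C57BL/6 mice (BomTac substrain) was measured on 76 Agilent 2-colour mouse arrays, 1 array per mouse. Per the labels, each mouse had received 1 intratracheal instillation of 162 µg of Printex 90 carbon black nanoparticles (CBNP) or of the vehicle, water. RNA came from random sections of lung. The lung RNA was labelled with Cy5 and hybridised beside a common reference in Cy3, the Universal Mouse Reference RNA, a pool from 11 mouse cell lines. The reference makes ratios of separate arrays comparable but is a pool of cell lines and not lung tissue, so only differences between arrays are interpreted. Groups were taken from the labels: 2 treatments at 8 times (3 h, each of days 1 to 5, day 14 and day 42). Of the 16 groups, 12 held 5 mice and 4 held 4 mice (CBNP at days 1, 2 and 3, and vehicle at day 42). The design text speaks of 5 to 6 replicates and the extraction text of 80 mice, and 76 arrays were held here. The vehicle mice of each time were separate animals, so no comparison of a time shared controls with another time.

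Per the file headers, the authors extracted the images with Agilent Feature Extraction 11.0.1.1. The deposited file of each array gives the median pixel intensity of every spot and of its local background in both channels, neither normalised nor background-subtracted, and a processed intensity that was background-subtracted and dye-normalised. The deposited series matrix gives log2 ratios of Cy5 over Cy3. How the authors made that matrix is not given in the sources used here. Tested on the files, its columns had medians of -0.0418 to 0.0126 and correlated at 0.9956 to 0.9991 with a loess-normalised ratio without background subtraction, across probes within an array. Spots flagged in the deposited files as non-uniform or as population outliers were left out, 204 to 403 per array (20954 in all), and 0 probe values were saturated.

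The median intensities were background-corrected by the normexp method (offset 50), turned into log2 ratios and loess-normalised within each array (span 0.3) in limma 3.58.1 under R 4.3.3, with the data.table package, version 1.17.8. Spots of the same probe were averaged (432 of 55681 probes were spotted more than once). A probe was kept when it carried a gene symbol and its Cy5 signal was well above background, per the file headers' own test, on at least 4 of the 76 arrays. The probe with the brightest mean signal stood for each gene, which gave 18194 genes. Of the 28446 probes without a symbol, 21345 passed the filters. They were tested only in an added fit, adjusted together with the named genes. Signal over background differed between arrays. The share of probes well above background was 41.64% to 90.59% (median 55.39), median Cy5 intensity 73 to 236.5 and median local Cy5 background 59 to 75. The number of arrays limits the precision. Each array's highest correlation with another, across probes, was 0.9153 to 0.9825.

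A limma model with 1 coefficient per group was fitted over all 76 arrays, with moderated two-sided tests and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05 and a change of at least 1.5-fold. F tests had no fold minimum. The comparisons were CBNP against vehicle at each time, the treatment by time interaction (F test), the mean early effect (3 h, days 1 and 2) minus the mean of days 3 to 5, the effects of days 14 and 42 each minus that mean, differences among the 8 vehicle groups (F test), and vehicle at 3 h against the later vehicle groups. Genes called the same way early and late against the middle days were counted as 2-phase. Values after ± are limma standard errors, with 4 or 5 mice per group as above. Their variance was estimated per gene over all 16 groups together. They do not measure the spread of the mice compared, and with their p-values can be too small where exposed mice varied more. For Saa3 at day 1 the SD was 2.51 in 4 exposed and 0.79 in 5 vehicle mice, against a standard error of 0.69. Where a gene was well above background on 0 arrays of a group, its fold was computed in the Cy5 channel alone against the lowest signal counted as well above background on those arrays, and is written "at least".

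35 gene lists, some of them sharing members, were tested at each time with camera (preset correlation 0.01), adjusted over all 280 tests. The lists were tested again with a correlation estimated from the arrays, and again without members shared with another list. They were neutrophil markers, neutrophil chemoattractants and acute cytokines, monocyte and lymphocyte chemokines, acute phase proteins, metallothioneins and Nrf2 targets, aryl hydrocarbon receptor targets, p53 targets, immediate early genes, glucocorticoid-responsive genes, circadian clock genes, mitotic and replication genes, cholesterol synthesis and uptake, interferon-stimulated genes, antigen presentation by MHC class II, complement, lysosome and phagocytosis, alternative macrophage activation and type 2 response, and extracellular matrix and remodelling. The cell type lists covered monocyte and recruited macrophage, alveolar macrophage, eosinophil and mast cell, B cell, plasma cell, T and NK cell, thymocyte, alveolar type 2, alveolar type 1, club, mucous, ciliated, endothelial, cardiac muscle, skeletal muscle, adipocyte and erythroid markers. Members were also tested with p-values adjusted over the list alone. Each mouse's list score, the mean log2 ratio of the measured members, was compared between arms by an exact two-sided permutation test. The smallest p it can give is 0.00794 for 5 against 5 mice and 0.0159 for 4 against 5.

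The text names, per time, the 6 highest and 4 lowest called changes among genes whose exposed mice all lay beyond all vehicle mice, up to 4 called members per list, or up to 2 members with the smallest p where no member was called. Where the results speak of the highest or lowest folds of a time, they mean those among genes without such overlap. For the phase, interaction and vehicle results it names up to 6 genes per direction with the smallest adjusted p (10 for F tests). It adds a panel of 20 inflammation, particle-response and lung genes. Some genes within this rule are not reported here. The model, the comparisons, the lists, this rule and the alternatives were fixed before the data were examined, except 4 alternatives added after seeing the data: without the 3 arrays that had 87.55% to 90.59% of probes well above background, without slides 1 and 2, with that percentage as a covariate, and with unnamed probes tested too. The other alternatives were Agilent's processed signals, the series matrix values, a further between-array scaling of intensities, the Cy5 channel alone, no filter, a filter of 38 arrays, the mean of a gene's probes, slide (random or fixed) and scan day as terms, a trended and robust variance, a fit of the 2 groups alone, no fold minimum, and leaving out each array in turn. The arrays lay on 10 slides of 6 to 8, scanned on 6 days, and 36 pairs of slide and time held both arms. The consensus correlation within slides was 0.193.

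The pipeline was tested on simulated data. Of 67 genes set to change 1.5-fold, 41.8% were called at group sizes of 4 against 5 and of 5 against 5. At 2-fold 100% and 97% were called, at 4-fold 100%, and of unchanged genes 0.0222% and 0.00556%. In simulated data without any change, 0 genes were called by limma over 14 results. The simulated noise was independent between genes and arrays, without slide effects or high-signal arrays, so these rates need not hold in the real data. At 1.5-fold the fold minimum itself also limits the share called.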

Results

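Gene expression was measured in the lungs of 76 mice, 39 given vehicle and 37 given 162 µg of carbon black nanoparticles (CBNP), at 3 h, on each of days 1 to 5, and on days 14 and 42 after a single instillation. Each group held 5 mice, or 4 for CBNP at days 1, 2 and 3 and for vehicle at day 42. The arrays had 41.64% to 90.59% of probes well above background, and 73 to 236.5 as median Cy5 intensity. The series title names an inflammatory response with 2 phases, so the comparisons ask which genes differed from vehicle at each time and whether the late response stood apart from the middle days. Replicates are numbered within their group.

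Inflammatory genes such as Saa3 and Cxcl5 were higher in exposed lungs early and late, with few or no single genes called at days 3 to 5. The acute phase and chemokine lists were still shifted up at day 3 (0.42 to 0.58 and 0.35 to 0.72 on omitting single mice). By the contrasts against the middle days, 0 genes were called in 2 phases. limma called 557 genes at 3 h (425 higher, 132 lower), 47 at day 1 (36 and 11), 537 at day 2 (240 and 297), 3 at day 3 (3 and 0), 67 at day 14 (61 and 6) and 59 at day 42 (53 and 6). At days 4 and 5 it called 0 genes, with 800 and 1229 at an unadjusted p under 0.05. Saa3, an acute phase protein made in the lung, and Cxcl5, an epithelial neutrophil chemoattractant, were lowest at days 4 and 5 and not yet low at day 3. Saa3 changed by log2 2.90, 5.07, 3.62, 2.86, 1.03, 0.57, 3.23 and 3.12 in order of time, and Cxcl5 was at 2.27, 0.68 and 0.24 at days 3 to 5. Cxcl5 was well above background on only 0 to 4 vehicle arrays of each time, so its folds are set against groups partly or wholly at background. With slide as a fixed term the counts were 574, 54, 576, 23, 0, 0, 73 and 86 in order of time, and 557, 42, 518, 3, 67 and 59 of the called genes were called in both fits.

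**Figure D1:**
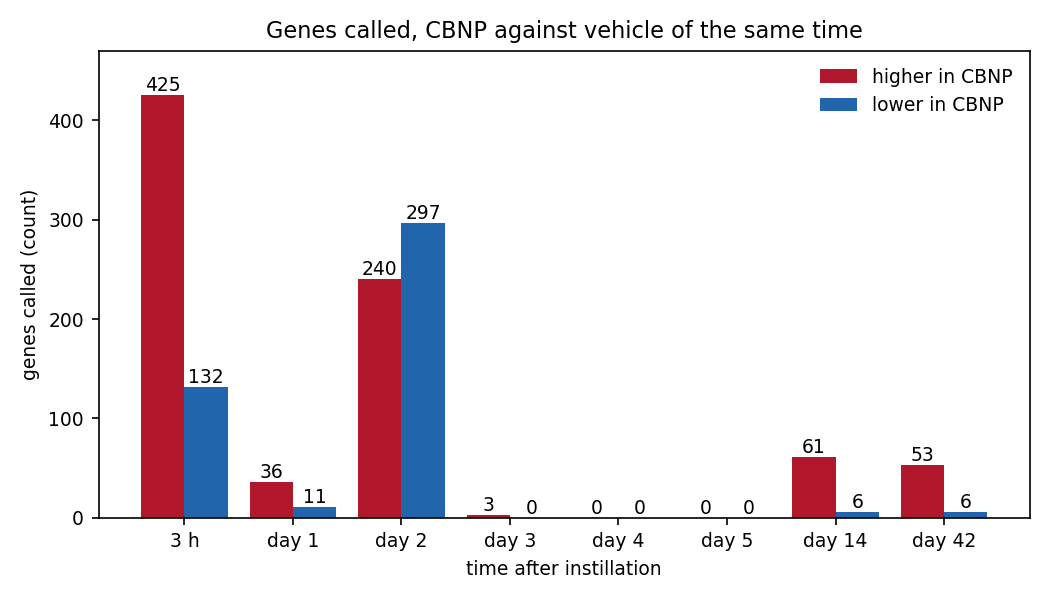
Genes called by limma in CBNP against vehicle lung at each of 8 times (x axis), as the number of genes higher and lower (y axis). The bars reach 425 higher at 3 h and 297 lower at day 2, and are at 0 at days 4 and 5.

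At 3 h, exposed lungs had raised genes of chemokines, acute phase proteins and metallothioneins, together with p53 targets and glucocorticoid-responsive genes. The lists of monocyte and lymphocyte chemokines, of acute phase proteins and of metallothioneins and Nrf2 targets were not called with an estimated correlation. Cxcl1, a neutrophil chemoattractant, rose 9.11-fold (log2 3.19 ± 0.39, adjusted p = 8.82e-09), and Mt2, a metal-binding protein, rose 9.75-fold (3.29 ± 0.41, 1.62e-08). Cdkn1a, the cell cycle inhibitor p21, rose 5.17-fold (2.37 ± 0.18, 1.45e-15). Among genes whose exposed mice all lay beyond all vehicle mice, others with the highest folds were Pdk4, which limits glucose oxidation (2.59 ± 0.46, adjusted p = 3.23e-05), Fkbp5, a glucocorticoid receptor chaperone (2.45 ± 0.29, 2.79e-09), Angptl4, a lipase inhibitor (2.44 ± 0.36, 6.34e-07) and Cebpd, a transcription factor (2.42 ± 0.38, 3.91e-06). The genes with the lowest called folds were Dbp, a clock output factor (-1.64 ± 0.42, adjusted p = 0.00494), Sox4, a developmental transcription factor (-1.32 ± 0.17, 2.04e-08), Rnf186 (-1.21 ± 0.18, 1.11e-06) and Itprid1 (-1.03 ± 0.23, 0.00131). All 11 lay in the same direction in 5 of 5 slides holding both arms. The calls of Rnf186 (log2 -0.53, adjusted p = 0.551, with Agilent's processed signals) and Itprid1 (-0.65, 0.116, from Cy5 alone) ended with another scaling.

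Among 15 neutrophil chemoattractants and acute cytokines 8 rose at 3 h (8 adjusted over the list alone), with Cxcl1, Cxcl5 (log2 2.98 ± 0.51), the cytokine Il6 (2.05 ± 0.31) and the chemokine Ccl3 (1.18 ± 0.19) among them. Of 13 glucocorticoid-responsive genes 11 rose (11 adjusted over the list alone), and their mean change was 1.76. Of 14 p53 targets 4 rose and 1 fell (4 and 1 adjusted over the list alone), among them Cdkn1a, the death receptor Fas (1.64 ± 0.13), Trp53inp1 (0.93 ± 0.17) and the stress cytokine Gdf15 (0.81 ± 0.16). These 3 lists were called with the preset correlation (adjusted p = 5.19e-11, 1.32e-18 and 6.83e-05) and with an estimated one (0.0188, 0.0021 and 0.00379). Of 13 monocyte and lymphocyte chemokines 5 rose (6 adjusted over the list alone; mean 0.86, adjusted p = 1.62e-05, but 0.306 with an estimated correlation), with Cxcl10 (1.93 ± 0.36), Ccl2 (1.81 ± 0.41) and the eosinophil chemokine Ccl11 (1.52 ± 0.25). Of 23 acute phase proteins 8 rose (9 adjusted over the list alone; 0.67, 3.12e-06, but 0.274 with an estimated correlation), with Saa3 (2.90 ± 0.65), Saa2 (2.44 ± 0.35), Saa1 (1.91 ± 0.39) and the haem carrier Hpx (1.34 ± 0.25). Of 22 metallothioneins and Nrf2 targets, genes of metal binding and antioxidant defence, 6 rose (6 adjusted over the list alone; 0.56, 7.52e-07, but 0.0617 with an estimated correlation), with Mt2, Mt1 (2.76 ± 0.30) and the antioxidant Srxn1 (1.29 ± 0.16).

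Of 16 immediate early genes, the first to answer a stimulus, 4 rose at 3 h (4 adjusted over the list alone; mean 0.52, adjusted p = 2.53e-05), with Fosb (1.25 ± 0.24), Egr2 (1.20 ± 0.20) and Atf3 (1.11 ± 0.24). Of 24 extracellular matrix and remodelling genes 5 rose (mean 0.32, adjusted p = 0.0111), with the matrix protein Thbs1 (1.83 ± 0.31), Timp1, an inhibitor of matrix proteases (1.53 ± 0.39), and Ccn2 (1.1 ± 0.22). Of 23 neutrophil markers 1 rose, the decoy receptor Il1r2 (1.32 ± 0.21), with a list mean of 0.40 (adjusted p = 0.00349). These 3 lists had adjusted p = 0.347, 0.421 and 0.529 with an estimated correlation. Among B cell markers 2 of 12 fell, the complement receptor Cr2 (-0.95 ± 0.22) and Ms4a1 (-0.67 ± 0.19), and the list shifted down (mean -0.28, adjusted p = 0.00706). That list's adjusted p was 0.549 with an estimated correlation, and its call ended without CBNP replicate 1 (mean -0.22). Among ciliated cell markers 2 of 10 fell, and the list shifted down (-0.41, adjusted p = 0.00102). Its adjusted p was 0.43 with an estimated correlation, and B cell and ciliated calls both ended with Agilent's processed signals.

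The aryl hydrocarbon receptor list, which combustion particles can induce through adsorbed hydrocarbons, was not called at 3 h (mean 0.25, adjusted p = 0.104), though its member Tiparp rose (0.88 ± 0.12, 3.36e-07) and Cyp1a1 was at 0.39 (0.146). Circadian clock genes moved both ways: Per1 (1.5 ± 0.47, adjusted p = 0.0279) and Arntl (0.85 ± 0.24, 0.0125) rose, Dbp and Per3 (-0.80 ± 0.20, 0.00414) fell, and the list mean was -0.07 (0.355). Per1 lost its call from Cy5 alone, without slides 1 and 2, and without any 1 of CBNP replicates 2 and 4 and vehicle replicates 1 and 5 (log2 1.39 to 1.61 over all omissions). The chemokine Ccl7 rose (1.69 ± 0.48, 0.0133), a call that ended without any 1 of CBNP replicates 3 and 5 and vehicle replicates 1 and 3 (1.28 to 2.39). In the cholesterol list 2 of 26 members rose (mean 0.15, adjusted p = 0.127), among them Pmvk (1.03 ± 0.18), and in the T and NK cell list 1 of 21, Il7r (0.92 ± 0.18; list 0.19, 0.0629). Panel genes not called were Cxcl2 (log2 0.50), Il1b (0.57), Tnf (0.22), Lcn2 (0.39), Mmp12 (0.01), Hmox1 (0.40), Marco (0.30), Sftpc (0.07) and Scgb1a1 (-0.11). With Agilent's processed signals 836 genes were called at 3 h, 60.8% of them higher, against 76.3% in the first fit. In 975 genes (5.36%, by chance 0.794%) exposed and vehicle mice did not overlap.

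At day 1 fewer genes were called than at 3 h, and acute phase proteins were the only list called with an estimated correlation as well. Saa3 rose 33.5-fold (log2 5.07 ± 0.69, adjusted p = 2e-06), and Saa1, a related serum amyloid protein, rose by 2.63 ± 0.42 (9.65e-05). The phospholipase Pla1a (1.41 ± 0.16, 4.26e-09), the secreted epithelial protein Clca3a1 (1.23 ± 0.14, 4.26e-09) and the iron-binding defence protein Lcn2 (1.56 ± 0.27, 0.000373) rose, and the matrix protein Thbs3 fell (-0.88 ± 0.13, 2.97e-05). Saa3 was higher in 4 of 4 and Lcn2 in 3 of 4 slides holding both arms. In Saa1 and Lcn2, and in Timp1 and Saa2 below, exposed and vehicle mice overlapped. The genes that follow each lost their call without at least 1 mouse. Without CBNP replicate 4 these were the serpin Serpina3m (1.46 ± 0.30, then 1.08), Timp1 (1.97 ± 0.41, then 1.30), Saa2 (at least 3.81-fold) and Krtap17-1 (-1.22 ± 0.25, then -1.15). Without CBNP replicate 1 they were the clock repressor Nr1d1 (1.22 ± 0.24, then 0.98), the pantetheinase Vnn3 (1.15 ± 0.23, then 1.01) and the interferon-induced GTPase Gbp4 (-1.14 ± 0.25, then -1.01). Spon2, a matrix protein (-1.17 ± 0.29, 0.045), lost it in 8 of 9 omissions, all but CBNP replicate 3 (-1.40 to -0.91), and Hmox1, the haem-degrading enzyme (0.69 ± 0.17, 0.0412), in 6 of 9 (0.53 to 0.79; CBNP replicates 1, 3 and 4, vehicle replicates 1, 2 and 5).

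Of 23 acute phase proteins 8 rose at day 1 (10 adjusted over the list alone), with Saa3, Saa1, Saa2 and Orm2 (1.70 ± 0.30), and the list mean was 0.89 (adjusted p = 2.95e-21, and 0.00398 with an estimated correlation). The other calls were lost with an estimated correlation, whose adjusted p stands last in what follows. Neutrophil chemoattractants and acute cytokines shifted up by 0.50 (3.43e-06, adjusted p = 0.128 with an estimated correlation), with 1 member called, the growth factor Csf2 (1.09 ± 0.21), and 4 adjusted over the list alone. Monocyte and lymphocyte chemokines shifted up with 0 members called by limma and 5 adjusted over the list alone (0.58, 0.28 to 0.81 on omissions, 1.03e-05, 0.293), and cholesterol synthesis (0.18, 0.12 to 0.24 on omissions, 3.7e-05, 0.365) and recruited macrophage markers (0.22, 0.00278, 0.451) shifted up with 0 members called too. Neutrophil markers (0.33, 0.21 to 0.42 on omissions, 4.1e-06, 0.306; 1 called, Il1r2 at 0.97), clock genes (0.33, 0.000382, 0.21; 2 called, Nr1d1 and Nr1d2, the latter at 0.85) shifted up as well. Complement was called up with a mean of only 0.01 (0.0351, 0.574; 1 member called, Cfb at 0.78), and that mean was below 0 in some omissions. Il1r2, Nr1d2 and Cfb lost their calls in 6, 7 and 5 of 9 omissions. Cardiac muscle markers, from heart muscle that surrounds large lung veins, shifted down by 1.72 in the mean (-1.72, 4.2e-06, 0.408), lower in 4 of 4 slides with both arms. Club cell markers shifted down (-0.72, 0.00193, 0.365), with 1 of 12 called, the retinal dehydrogenase Aldh1a1 (-0.71 ± 0.17, a call lost without CBNP replicate 4, -0.58, or vehicle replicates 1 or 3). Aryl hydrocarbon receptor targets (-0.24, 0.00552, 0.0617), mucous cell (-0.76, 0.0395, 0.661), adipocyte (-0.82, 0.0331, 0.685), T and NK cell (-0.18, 0.00216, 0.481), immediate early (-0.34, 0.0209, 0.664) and interferon-stimulated genes (-0.11, 0.0239, 0.711) shifted down too. Calls of the immediate early (-0.49 to -0.26), interferon (-0.23 to -0.04), complement (-0.08 to 0.08), mucous (-0.95 to -0.40) and adipocyte lists (-1.06 to -0.46) ended in 4 or 5 of 9 omissions each, CBNP replicate 1, 2 or 4 among them, and that of T and NK cells without CBNP replicate 2 (-0.10). Glucocorticoid-responsive genes were at 0.02 (0.751).

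Cxcl5 was at 2.12 ± 0.54 at day 1 (adjusted p = 0.0506, and 0.0451 with slide as a term). Cxcl1 (1.03), Ccl2 (1.1), Ccl7 (1.29), Il6 (0.59) and Mt2 (0.75) were not called. The count of 47 genes, from 1547 at an unadjusted p under 0.05, was 24 without CBNP replicate 4 and 29 without vehicle replicate 1, and 12 without slides 1 and 2, where 9 of 22 named calls were kept. The share of higher genes was 65.9% with Agilent's processed signals against 76.6%. Exposed and vehicle mice did not overlap in 544 genes (2.99%, by chance 1.59%).

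At day 2, many genes of cell division, Saa3, Saa1 and Cxcl5 were raised, and a few markers of endothelium and of T and NK cells were lower, though 0 lists were called with an estimated correlation. Saa3 rose 12.3-fold (3.62 ± 0.69, adjusted p = 0.000313) and Cxcl5 10.7-fold (3.41 ± 0.54, 2.36e-05; 2 of 5 vehicle arrays well above background). The centromere protein Cenpi rose 4.52-fold (2.18 ± 0.34, 2.36e-05), Lrr1, of replication disassembly, by 1.71 ± 0.28 (3.68e-05), Saa1 by 1.75 ± 0.42 (0.00359), Lcn2 by 1.54 ± 0.27 (7.48e-05) and Ssxb10 at least 4.05-fold (3.72e-05). The lowest called folds were those of Gpr182, an endothelial chemokine scavenger (-1.67 ± 0.29, 0.000114), Fam205a2 (-1.24 ± 0.18, 6.73e-06), Slc35g2 (-1.24 ± 0.19, 2.04e-05) and the eosinophil ribonuclease Ear1 (-1.22 ± 0.28, 0.00285, a call lost without CBNP replicate 2, -0.82). Each had its direction in 4 of 4 slides with both arms. In 2 of the 4 exposed arrays of this day 89.69% and 90.59% of probes were well above background (CBNP replicates 2 and 4), and without these and 1 such vehicle array of day 5, which leaves 2 exposed mice, 8 genes were called, 6 of them in both fits, with 1 of 47 named calls kept, Cxcl5. With the percentage as a covariate 20 of the 47 were kept, and from Cy5 alone 32, with Gpr182 at 0.49 and Slc35g2 at 0.15.

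Of 34 mitotic and replication genes 20 rose at day 2 (20 adjusted over the list alone), and the list mean was 0.81 (adjusted p = 3.14e-28, but 0.062 with an estimated correlation), higher in 4 of 4 slides with both arms. The survival and division factor Birc5 (1.74 ± 0.37), the anaphase activator Cdc20 (1.54 ± 0.34), the proliferation marker Mki67 (1.52 ± 0.33) and the cyclin Ccna2 (1.5 ± 0.30) had the largest changes. Chemoattractants and acute cytokines (2 of 15 rose, mean 0.56, 1.09e-06), chemokines (3 of 13 rose, 0.61, 0.000119), acute phase proteins (5 of 23 rose, 0.61, 1.61e-08) and lysosome and phagocytosis genes (2 of 20 rose, 0.20, 0.12 to 0.27 on omissions, 0.000181) shifted up. With an estimated correlation the adjusted p was 0.105, 0.35, 0.143 and 0.35 for these 4. Adjusted over the list alone, 2, 4, 6 and 2 of their members rose, among them Ccl2 (1.60 ± 0.43), Cxcl1 (1.47 ± 0.41), Ccl9 (0.89 ± 0.24), and Gpnmb, a glycoprotein of lipid-laden macrophages (0.88 ± 0.21). Timp1 rose by 1.63 ± 0.41 in the matrix list (1 of 24, mean 0.14, 0.0413, adjusted p = 0.565 with an estimated correlation). The calls of Cxcl1 (1.29 and 1.28), Ccl2 (1.25 and 1.29), Ccl9 (0.76 and 0.76) and Timp1 (1.34 and 1.37) ended without CBNP replicate 2 and without 4, that of Gpnmb without replicate 4 (0.71), and that of Cdc20 without replicate 2 (1.15). The matrix list lost its call without CBNP replicate 2 (0.10) or vehicle replicates 2 (0.12) or 3 (0.10). Ccl7 (1.57 ± 0.51, 0.0336) lost its call in 6 of 9 omissions (1.24 to 2.06; CBNP replicates 2 and 4, vehicle replicates 1 to 4).

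Of 13 endothelial markers 4 fell at day 2 (mean -0.40, adjusted p = 0.000501), with the junction protein Pecam1 (-0.80 ± 0.16) and the surface protein Emcn (-0.76 ± 0.17). T and NK cell markers shifted down with 3 of 21 fallen (4 adjusted over the list alone; -0.38, 0.00043), among them the receptor chain Cd3d (-0.94 ± 0.20). B cell markers shifted down with 0 members called by limma and 3 adjusted over the list alone (-0.47, 0.000333), and alveolar macrophage markers with 5 of 16 fallen (-0.45, 0.00836), among them Ear1 and Siglecf, a receptor of alveolar macrophages and eosinophils (-1.17 ± 0.31). With an estimated correlation the adjusted p of these 4 lists was 0.277, 0.397, 0.365 and 0.489. The alveolar macrophage list's call ended without CBNP replicate 2 (-0.25) and with slide as a term (adjusted p = 0.0502), and from Cy5 alone the endothelial, B cell and macrophage calls ended. The neutrophil receptor Fpr1 fell (-1.04 ± 0.24) and the lectin Clec4d rose (0.93 ± 0.30, 0.0336, a call lost in 5 of 9 omissions), with their list of neutrophil markers not called, the mucus protein Fcgbp fell (-0.95 ± 0.29; 0.08 from Cy5 alone), and Sult1a1 (-0.99 ± 0.18) fell in the glucocorticoid list. Fpr1 lost its call without CBNP replicate 2 (-0.66), as did Siglecf (-0.88), and Fcgbp lost it without CBNP replicate 2 or 4 or vehicle replicate 5 (-1.28 to -0.67). Il6 (0.55), Tnf (0.26) and Mt2 (0.59) were not called. The count of 537 was 998 without CBNP replicate 1, 186 without replicate 2 and 325 without replicate 4. Higher genes made up 44.7%, but 72.6% from Cy5 alone (1081 and 409) and 59.2% with the series matrix values (287 and 198). Exposed and vehicle mice did not overlap in 1514 genes (8.32%, by chance 1.59%).

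At day 3 only Ly6f, a lymphocyte antigen 6 family protein (1.59 ± 0.30, adjusted p = 0.0176), Noxo1, an organiser of NADPH oxidase (1.37 ± 0.25, 0.0114), and Lcn2 (1.26 ± 0.27, 0.0417) were called by limma, each higher in 4 of 4 slides with both arms, from 1851 genes at an unadjusted p under 0.05. The 3 genes were also called at days 1, 2, 14 and 42. All 3 calls ended with Agilent's processed signals and without slides 1 and 2. The count was 0 without CBNP replicate 1 or 3 or vehicle replicate 1, 1 without vehicle replicate 4, 5 without vehicle replicate 2, 8 without CBNP replicate 2, and 84 without CBNP replicate 4. Saa3 (2.86 ± 0.69, adjusted p = 0.105) and Cxcl5 (2.27 ± 0.54, 0.0991) were not called, though with slide as a term they were (0.0352 and 0.0307), and Marco, a particle-binding receptor of macrophages, was at 0.91 (0.239). Mitotic genes stayed shifted up (0.47, 3.65e-16), with 0 members called by limma and 12 adjusted over the list alone, led in p by Rrm2 (1.00) and Aurka (0.71). Acute phase proteins (0.50, 3.68e-07), chemokines (0.53, 6.29e-05), chemoattractants (0.34, 0.00552), neutrophil markers (0.22, 0.0203), lysosome genes (0.21, 0.00017), recruited macrophage markers (0.24, 0.00349), clock (0.25, 0.0378), cholesterol (0.11, 0.0209) and ciliated cell genes (0.27, 0.00595) shifted up. MHC class II (-0.20, 0.00649), B cell (-0.24, 0.00159), T and NK cell (-0.14, 0.00801) and endothelial genes (-0.12, 0.027) shifted down. Of these 14 lists 0 were called with an estimated correlation, with adjusted p = 0.238 for mitotic genes, 0.209, 0.347, 0.397, 0.664, 0.35, 0.469, 0.508, 0.682 and 0.548 for the other raised lists, and 0.356, 0.448, 0.577 and 0.508 for the lowered ones. Mitotic (0.27 to 0.65), acute phase (0.42 to 0.58), chemokine (0.35 to 0.72) and B cell lists (-0.30 to -0.17) kept their calls without any 1 mouse, and each of the others lost it without at least 1. Without CBNP replicate 1 these were chemoattractants (0.20), neutrophil markers (0.16), lysosome (0.14), MHC class II (-0.17), cholesterol and endothelial genes. Without CBNP replicate 3 they were recruited macrophage markers (0.11), clock and cholesterol genes, without CBNP replicate 2 ciliated genes, and without vehicle replicate 4 T and NK cell markers (-0.09) and clock genes. Over all omissions cholesterol genes were at 0.01 to 0.20, endothelial genes at -0.20 to -0.05, ciliated genes at 0.14 to 0.44 and clock genes at 0.18 to 0.30. Exposed and vehicle mice did not overlap in 328 genes (1.8%, by chance 1.59%).

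At days 4 and 5, when limma called 0 genes, camera called 16 and 12 lists, 0 of them with an estimated correlation. Mitotic genes were shifted up at both days (0.29, adjusted p = 8.39e-10, and 0.23, 4.4e-05), as were recruited macrophage markers (0.21, 4.4e-05, and 0.17, 0.00592) and matrix genes (0.16, 0.000333, and 0.15, 0.00986). With an estimated correlation their adjusted p was 0.365 and 0.624, 0.315 and 0.508, and 0.261 and 0.408. Interferon-stimulated genes were shifted up at day 5 (0.48, 2.15e-18, adjusted p = 0.0518 with an estimated correlation), with 6 of 21 members adjusted over the list alone and the antiviral genes Oasl2 at 0.78 (0.345) and Xaf1 at 0.51 (0.524). B cell (0.26, 0.000136, 0.35 with an estimated correlation) and endothelial markers (0.17, 0.00586, 0.365), lower at days 2 and 3, were shifted up at day 5, and both kept their calls without any 1 mouse (0.17 to 0.35 and 0.13 to 0.21). Club cell markers were shifted down at both days (-0.55, 0.00147, and -0.45, 0.0146), and cholesterol synthesis too (-0.17, 3.55e-07, and -0.09, 0.011), with adjusted p = 0.359, 0.52, 0.297 and 0.664 with an estimated correlation. At day 4 the omissions gave -0.83 to -0.39 for club cells and -0.21 to -0.11 for cholesterol synthesis, all called. At day 5 the recruited macrophage call ended without vehicle replicate 3 (0.11), the matrix call without CBNP replicate 4 (0.14) or vehicle replicate 5 (0.14), the cholesterol call without vehicle replicate 4 (-0.07), and the club cell call without CBNP replicate 4 or vehicle replicates 3 or 4 (-0.60 to -0.26). At day 4 complement (0.12, 0.000783, 0.344 with an estimated correlation), interferon-stimulated genes (0.15, 0.00918, 0.677), neutrophil markers (0.14, 0.0373, 0.683) and chemokines (0.18, 0.0395, 0.677) were called up too, and lost their calls in 1, 4, 5 and 6 of 10 omissions (0.07 to 0.19, 0.09 to 0.23, -0.10 to 0.34 and 0.15 to 0.21), with neutrophil markers turning down without CBNP replicate 1 (-0.10). Clock genes were down at both days (-0.21, 0.000181, 0.183, and -0.14, 0.0231, 0.452), a call that held in all omissions at day 4 (-0.40 to -0.12) and was lost in 2 of 10 at day 5 (-0.21 to -0.10). So were ciliated cell markers (-0.18, 0.0132, 0.624, and -0.18, 0.0234, 0.664), whose calls ended in 3 of 10 omissions at each day (-0.33 to -0.10 and -0.28 to -0.10), and which turned up at day 5 with Agilent's processed signals (0.08). Immediate early genes were down at day 4 (-0.15, 0.0477, 0.696) and up at day 5 (0.32, 0.00349, 0.52), calls lost in 6 and 2 of 10 omissions (-0.28 to -0.01 and 0.22 to 0.43), and cardiac genes were down at day 5 (-0.57, 0.0146, 0.712), lost in 4 (-0.89 to -0.17). At day 4 erythroid markers (0.21, 0.00986, 0.169 with an estimated correlation) were up and plasma cell markers (-0.12, 0.0164, 0.203) and metallothioneins and Nrf2 targets (-0.11, 0.00276, 0.347) down. Skeletal muscle markers were up at day 4 (1.18, 4.47e-15, 0.0768 with an estimated correlation), but at 0.02 and not called without CBNP replicate 5. Saa3 (1.03 and 0.57), Cxcl5 (0.68 and 0.24) and Il1b (0.67 at day 5) were not called. Exposed and vehicle mice did not overlap in 119 and 138 genes (0.654% and 0.758%, by chance 0.794%), and at day 4 1 gene was called without vehicle replicate 5.

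At day 14, recruited macrophage, lysosome, complement and chemokine genes and p53 targets were shifted up with either correlation. Saa3 rose 9.41-fold (3.23 ± 0.65, adjusted p = 0.003), the anion exchanger Slc26a4, which sets the acidity of airway fluid, by 3.10 ± 0.55 (0.000478), and Cxcl5 at least 5.32-fold (0.00234). The lymphocyte antigen 6 genes Ly6f (2.87 ± 0.29, 1.69e-10) and Ly6i (2.83 ± 0.33, 2.22e-08) and the small secreted protein Wfdc17 (1.98 ± 0.32, 6.88e-05) rose, as did Lcn2 (1.67 ± 0.25, 1.43e-05) and Marco (1.60 ± 0.27, 0.000148). The lowest called folds were those of Asgr1, a glycoprotein receptor (-1.05 ± 0.26, 0.035), Prickle1, of planar cell polarity (-0.78 ± 0.16, 0.00457), the endothelial chaperone Hspa12b (-0.75 ± 0.14, 0.00135) and the platelet chemokine Ppbp (-0.68 ± 0.18, 0.0473). Each had its direction in 5 of 5 slides with both arms. Asgr1 lost its call in 7 of 10 omissions (-1.14 to -0.93; kept without CBNP replicate 2 or vehicle replicates 2 or 4), Ppbp in all but CBNP replicate 5 (-0.80 to -0.61), and Prickle1 without CBNP replicate 3 (-0.64). Cxcl1 (1.58 ± 0.39, 0.0317) lost it in 7 of 10 (1.47 to 1.78; kept without CBNP replicates 2 or 5 or vehicle replicate 2).

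Of 17 monocyte and recruited macrophage markers 6 rose at day 14 (7 adjusted over the list alone; mean 0.56, adjusted p = 1.02e-22), with Ms4a7 (1.29 ± 0.19), the lipid receptor Trem2 (1.27 ± 0.22) and Gpnmb (1.20 ± 0.20). Of 20 lysosome and phagocytosis genes 5 rose (5 over the list alone; 0.44, 1.55e-23), with the protease Ctsk (1.37 ± 0.21) and the acid phosphatase Acp5 (0.71 ± 0.14). Of 16 complement genes 4 rose (4 over the list alone; 0.36, 1.47e-16), with the central component C3 (0.90 ± 0.18) and C1qb (0.89 ± 0.19, called except without vehicle replicate 3, 0.77). Of 13 chemokines 4 rose (7 over the list alone; 0.86, 1.7e-16), with the monocyte chemokines Ccl8 (1.82 ± 0.34), Ccl9 (1.38 ± 0.22) and Ccl6 (0.95 ± 0.19). Of 14 p53 targets 1 rose, Gdf15 (0.74), and the list shifted up (0.23, 0.000113). All 5 lists were still called with an estimated correlation (adjusted p = 0.0021, 0.0021, 0.0021, 0.0139 and 0.00398), and each kept its call without any 1 mouse. Gdf15 itself lost its call without CBNP replicate 1 or 3 (0.66 to 0.86).

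Acute phase proteins also shifted up at day 14 (5 of 23 rose, 10 adjusted over the list alone; 0.59, 1.94e-12), with Itih4, a liver-type plasma protein (1.08 ± 0.24). So did chemoattractants (2 rose; 0.50, 1.07e-06), alveolar macrophage markers (2 of 16 rose; 0.40, 1.93e-08), genes of alternative macrophage activation (2 of 17 rose; 0.42, 0.000144), immediate early genes (1 rose; 0.54, 7.02e-08), cholesterol synthesis (0 members called by limma; 0.25, 5.19e-11), neutrophil markers (0 called; 0.30, 0.000148) and glucocorticoid-responsive genes (1 rose, Lcn2; 0.37, 0.00245). With an estimated correlation their adjusted p was 0.0573, 0.105, 0.0804, 0.21, 0.183, 0.128, 0.365 and 0.35. Alveolar type 2 markers, of surfactant-making cells, shifted up (0.15, 0.027, adjusted p = 0.47 with an estimated correlation), with Sftpc not called. Interferon (0.14, 0.0344, 0.721 with an estimated correlation) and adipocyte genes (0.31, 0.0183, 0.668) shifted up, and club (-0.45, -0.60 to -0.26 on omissions, 0.00345, 0.397), endothelial (-0.12, 0.00343, 0.35), B cell (-0.15, 0.0204, 0.649) and plasma cell markers (-0.12, 0.0133, 0.183) shifted down. The adipocyte mean was -0.59 without CBNP replicate 2 and not called without vehicle replicates 2 (0.16) or 5 (0.23). Interferon (0.09 to 0.18), B cell (-0.20 to -0.06) and alveolar type 2 calls (0.11 to 0.17) ended in 5, 3 and 4 of 10 omissions, CBNP replicates 1 or 2 among them, and the plasma cell call without vehicle replicate 1 (-0.08). Saa1 (1.12), Ccl2 (1.02), Ccl7 (1.25), Timp1 (0.78), Tnf (0.26), Mmp12 (0.27) and Per1 (0.83) were not called. The 67 genes, from 1135 at an unadjusted p under 0.05, were 40 without vehicle replicate 3, and 79.7% were higher with Agilent's processed signals against 91%. Exposed and vehicle mice did not overlap in 449 genes (2.47%, by chance 0.794%).

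**Figure D2:**
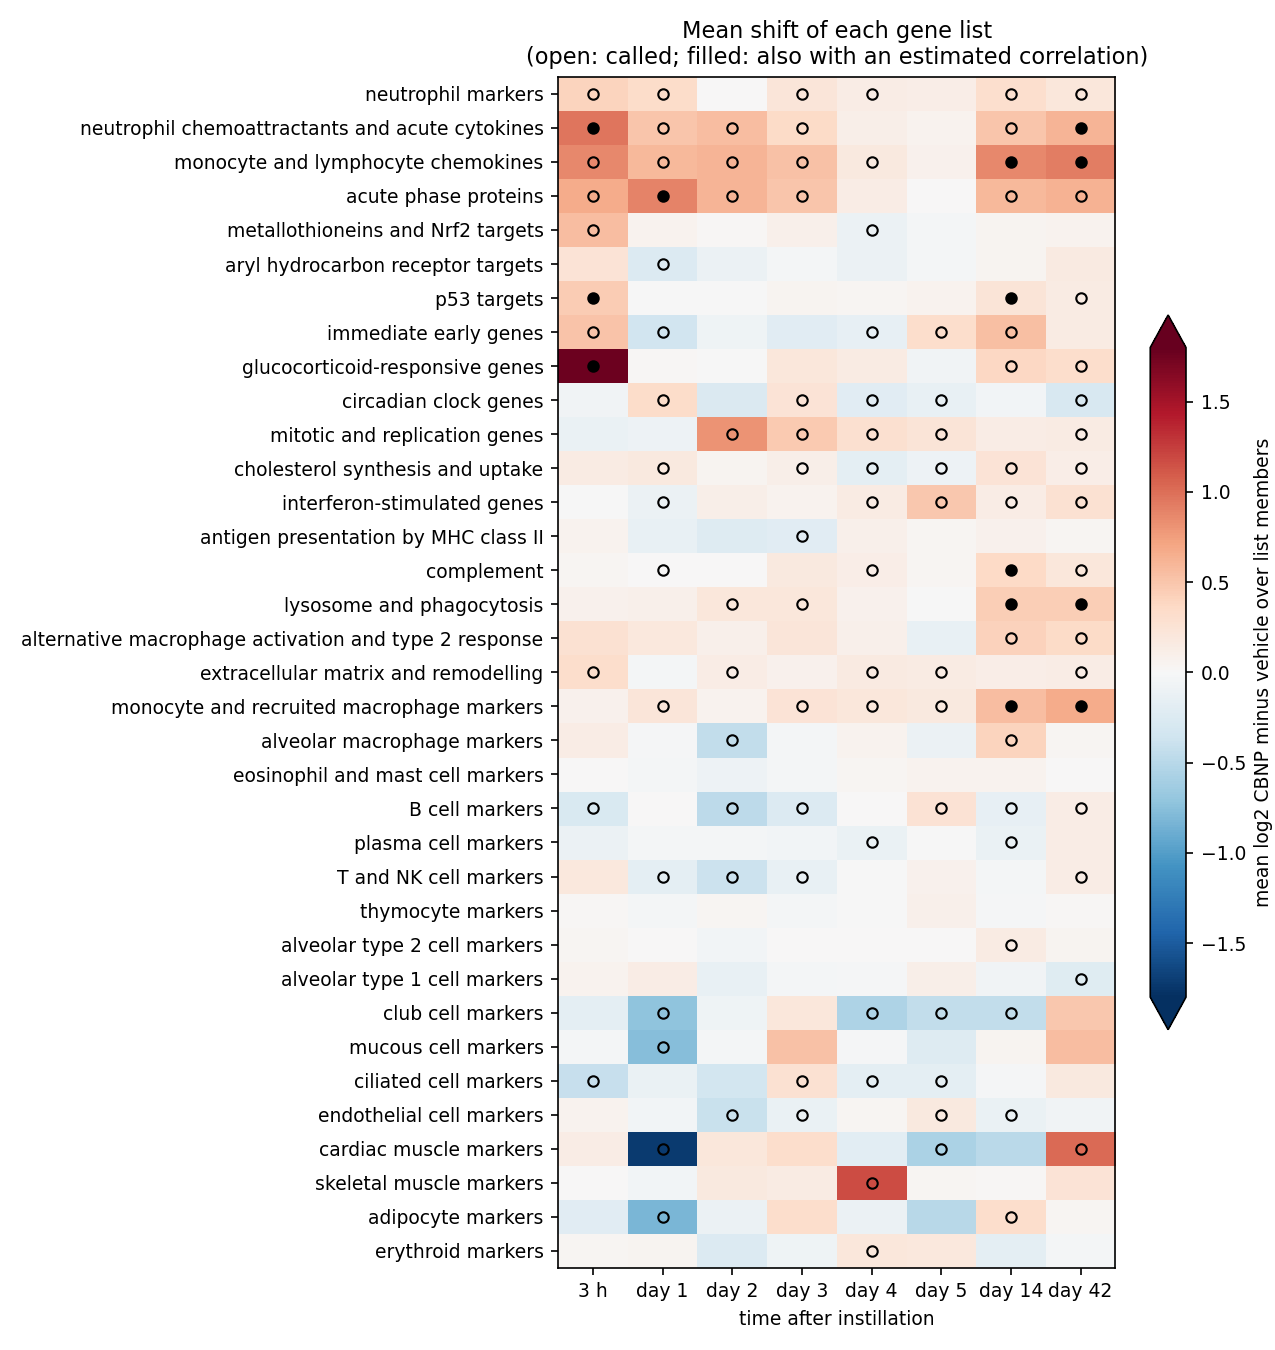
Mean log2 change, CBNP minus vehicle, of the measured members of 35 gene lists (vertical axis) at 8 times (horizontal axis), as colour. An open dot marks a list called by camera and a filled dot one also called with an estimated correlation, and monocyte and recruited macrophage markers stand at 0.56 and 0.67 at days 14 and 42.

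At day 42, recruited macrophage markers, lysosome genes, chemokines and chemoattractants were shifted up with either correlation. Cxcl5 rose 12.8-fold (3.68 ± 0.54, adjusted p = 6.87e-06; 1 of 4 vehicle arrays well above background), Saa3 8.7-fold (3.12 ± 0.69, 0.0124), Ly6i by 3.05 ± 0.35 (8.62e-09), Ly6f by 2.98 ± 0.30 (3.67e-10), Slc26a4 by 2.89 ± 0.59 (0.00392), Wfdc17 by 2.30 ± 0.34 (8.79e-06) and Lcn2 by 1.77 ± 0.27 (1.07e-05). The lowest called folds were those of Cst8, a cystatin (-0.92 ± 0.22, 0.0264), Bex2 (-0.90 ± 0.18, 0.00364), the matrix protein Tnxb (-0.74 ± 0.18, 0.0369) and Cys1, a ciliary protein (-0.66 ± 0.15, 0.017). Each had its direction in 4 of 4 slides with both arms. Bex2 lost its call without CBNP replicate 1 (-0.60), Saa3 without CBNP replicate 1 or vehicle replicates 1 or 2 (2.62 to 3.32), and Cst8, Tnxb and Cys1 in 6, 7 and 5 of 9 omissions (-1.05 to -0.81, -0.85 to -0.60 and -0.76 to -0.58), each including vehicle replicates 2, 3 and 4. Marco rose (1.18 ± 0.29, 0.0322), a call lost in 6 of 9 omissions (1.03 to 1.29; vehicle replicates 1 to 4, CBNP replicates 4 and 5). Mmp12, a macrophage elastase, passed the test with a change under 1.5-fold (0.51 ± 0.10, 0.0015).

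Of 17 monocyte and recruited macrophage markers 5 rose at day 42 (9 adjusted over the list alone; mean 0.67, adjusted p = 2.81e-24), with Gpnmb (1.78 ± 0.21), Trem2 (1.68 ± 0.23) and Ms4a7 (1.54 ± 0.20). Of 20 lysosome genes 3 rose (5 over the list alone; 0.44, 4.1e-19), with Ctsk (1.27 ± 0.22). Of 13 chemokines 3 rose (9 over the list alone; 0.92, 3.1e-15), with Ccl8 (2.13 ± 0.36) and Ccl9 (1.51 ± 0.24), and of 15 chemoattractants 2 (5 over the list alone; 0.61, 3.37e-10). These 4 lists were still called with an estimated correlation (0.0021, 0.00398, 0.0188 and 0.0261). Acute phase proteins (4 of 23 rose; 0.62, 5.81e-12), with Itih4 (1.47 ± 0.25), p53 targets (1 rose, Gdf15, 0.90 ± 0.17; 0.15, 0.0132), complement (0.21, 0.09 to 0.26 on omissions, 3.67e-06), interferon-stimulated (0.28, 0.15 to 0.36, 1.47e-05), alternative activation (0.34, 0.00434), glucocorticoid-responsive (0.31, 0.00521), matrix (0.14, 0.0194) and neutrophil genes (0.21, 0.0156) shifted up. For these 8 the adjusted p was 0.0617, 0.104, 0.128, 0.39, 0.356, 0.376, 0.479 and 0.657 with an estimated correlation. Mitotic (0.15, 0.00534, adjusted p = 0.729 with an estimated correlation), cholesterol (0.12, 0.00801, 0.653), T and NK cell (0.14, 0.00475, 0.529), B cell (0.13, 0.0427, 0.681) and cardiac genes (1.02, 0.00649, 0.682) shifted up, and clock (-0.29, 0.00531, 0.35) and alveolar type 1 genes (-0.22, 0.00603, 0.347), of gas-exchange epithelium, down. Without CBNP replicate 1 the mitotic (0.09), cholesterol (0.06) and cardiac calls (0.61) ended, without CBNP replicate 5 those of cardiac (0.58) and T and NK cell genes (0.09), without vehicle replicate 1 (0.08) or CBNP replicate 2 (0.14) that of matrix genes, and in 6 of 9 omissions that of B cells (0.08 to 0.20). Cxcl1 (1.44), Ccl2 (1.40), Ccl7 (1.59), Saa1 (1.24) and Tnf (0.31) were not called. The 59 genes, from 1537 at an unadjusted p under 0.05, were 26 without CBNP replicate 1 and 35, 33 and 36 without vehicle replicates 1, 2 and 4. Of 29 named genes 19 were called with Agilent's processed signals. Exposed and vehicle mice did not overlap in 863 genes (4.74%, by chance 1.59%).

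Over all lists and times 118 of 280 tests were called (82 up, 36 down), 13 of them with an estimated correlation and 110 with slide as a term. With members shared between lists left out, 105 tests were called. Shared members numbered 5 in the recruited macrophage list, 5 in chemokines, 4 in complement, 6 in alternative activation and 2 in lysosome genes. Gpnmb, for 1, stood in both the macrophage and lysosome lists, so these lists are not separate evidence. By exact permutation with adjustment over the lists 0 were called, but the smallest p that this test can give leaves it little room after adjustment. Eosinophil and mast cell markers and thymocyte markers were called at 0 times. In 27 of the 280 a list's median, mean and test differed in sign, and 0 of these were called.

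Genes called higher late overlapped with each other and with those called higher early more than independent lists would. Days 14 and 42 shared 35 higher genes (0.178 expected if independent) and 0 lower ones (0.00198). Higher genes were shared by 3 h and day 1 (14, 0.841 expected), 3 h and day 2 (14, 5.61), 3 h and day 14 (11, 1.42), 3 h and day 42 (9, 1.24), days 1 and 2 (8, 0.475), days 1 and 14 (9, 0.121), days 1 and 42 (5, 0.105), days 2 and 14 (14, 0.805) and days 2 and 42 (15, 0.699). Lower genes were shared by an early and a late time in 0 to 2 cases per pair. Over all genes the log2 changes correlated at 0.0592 to 0.401 between an early and a late time (0.0592 for 3 h and day 42, 0.096 for days 1 and 42), at 0.0258 between 3 h and day 2, and at 0.414 between days 14 and 42. Day 3 correlated at 0.352 with day 14 and at 0.511 with day 42, the highest value of any pair of times. Days 4 and 5 correlated with the late times at 0.149 to 0.294. Each time had its own vehicle mice.

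**Figure D3:**
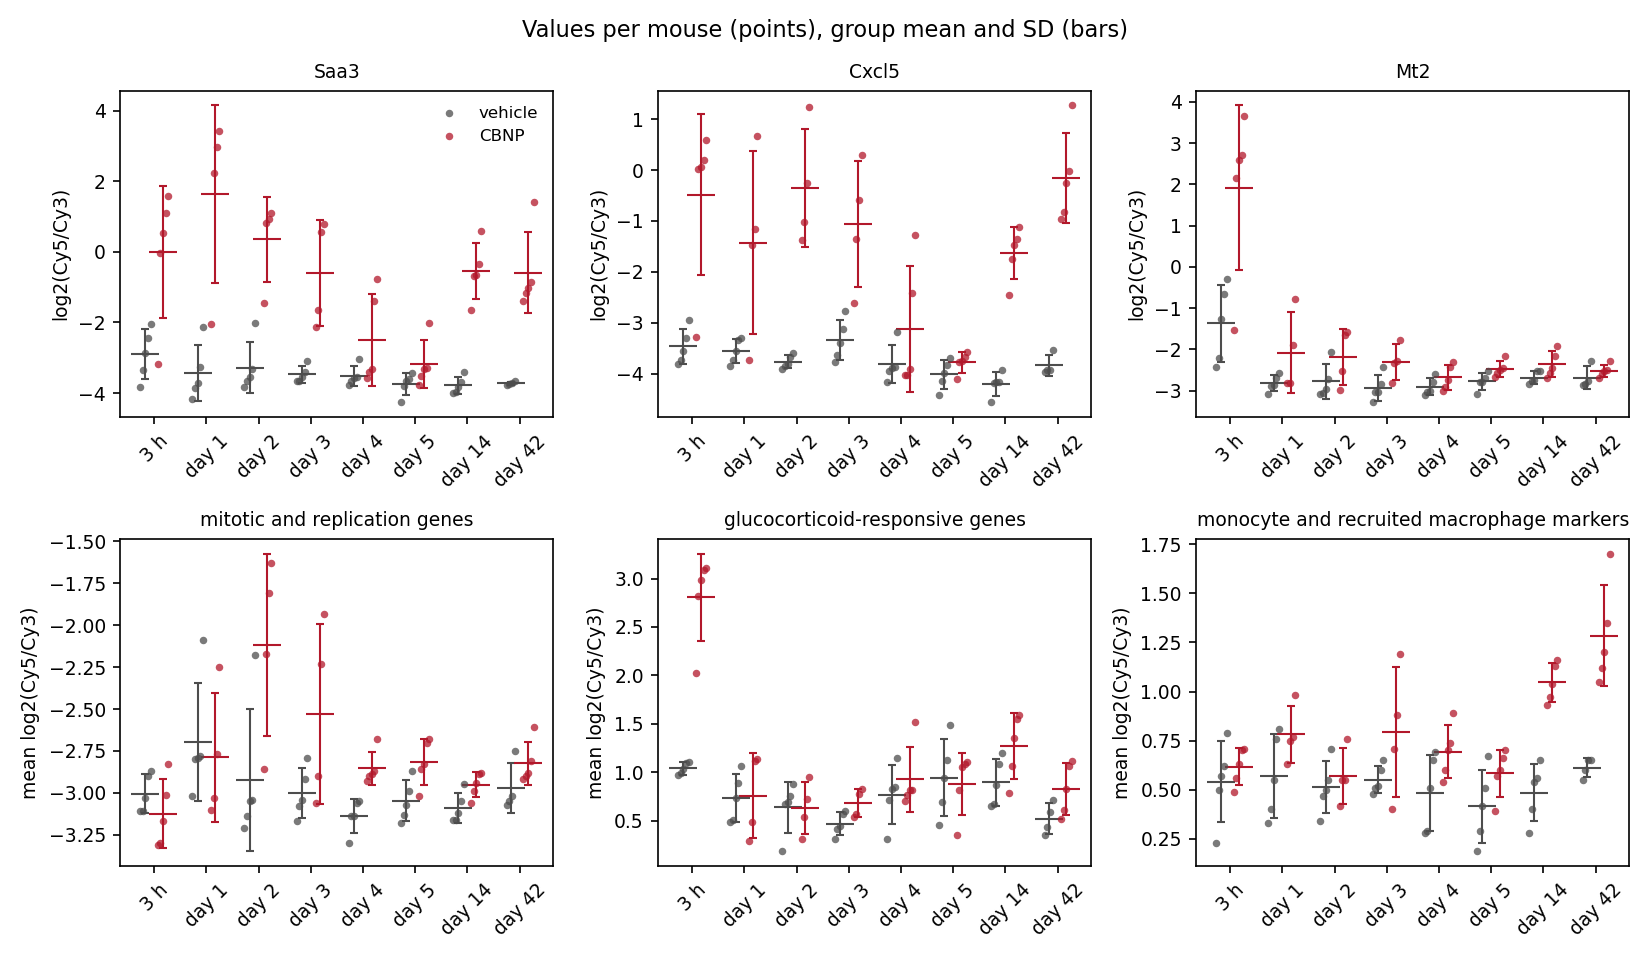
Log2 ratio of Cy5 over Cy3 in each mouse (y axis) against time (x axis) for Saa3, Cxcl5, Mt2 and the scores of the mitotic, glucocorticoid-responsive and recruited macrophage lists, with each group's mean and SD. Saa3 differed between arms by 5.07 at day 1, 0.57 at day 5 and 3.12 at day 42.

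The response differed over time in 1315 genes by limma's interaction test (3107 with slide as a term, 1315 in both fits). Among the 10 genes with the smallest p were several whose 3 h value was the highest: the survival factor Bcl2l1 (log2 1.58 at 3 h and -0.29 to 0.19 later, adjusted p = 4.37e-12), Fas (1.64), Cdkn1a (2.37), Rin3 (0.93) and Hif3a (2.22). Ly6f, highest at days 14 and 42, was among the same 10 genes. The count was 2048 without CBNP replicate 1 of day 2 and 846 without replicate 2.

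Against days 3 to 5, the early mean effect was higher in 24 genes and lower in 7, from 2534 at an unadjusted p under 0.05. Fkbp5 (1.40 ± 0.24, adjusted p = 0.00171), Ttc39c (0.63 ± 0.11, 0.00171), Serpina3m (1.25, 0.00524) and Saa2 (1.51, 0.00524) were higher, and Fam181b (-0.64 ± 0.11, 0.00254) and the death ligand Tnfsf10 (-0.79 ± 0.16, 0.00748) lower. The effect at day 14 was higher in 10 genes and lower in 4, with Ly6f (2.05 ± 0.33, 0.000988) and Asgr2 (0.79 ± 0.14, 0.00238) highest in rank and Ppbp (-0.96) among the lower. At day 42 it was higher in 9 and lower in 1, Bex2 (-0.95 ± 0.21, 0.0391), with the inhibitory-receptor relative Cd200r2 (1.00 ± 0.14, 4.86e-05), Ly6f (2.16 ± 0.35, 0.000386), Ly6i (2.30 ± 0.40, 0.00157), Ms4a7 (1.21), Gpnmb (1.26) and Trem2 (1.35) higher. With slide as a term the 3 counts were 56, 18 and 13, and 30, 14 and 10 genes were called in both fits. 0 genes were called the same way early and late by limma (0.0185 expected higher and 0.00192 lower if independent), and 0 again with the arrays of days 3 to 5 split between the contrasts. With slide as a random block and with scan day as a term 1 gene was called in both phases, Cxcl5, and without slides 1 and 2 there were 4 (Cxcl5, Gdf15, Lcn2 and Serpina3f).

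The counts against days 3 to 5 moved with single mice. The 31 early genes were 83 without CBNP replicate 1 of 3 h, 73 and 56 without CBNP replicate 1 of days 2 and 3, 55 without CBNP replicate 2 of day 1 and 53 without vehicle replicate 2 of 3 h. They were 20 without CBNP replicate 1 of day 1, replicate 2 of day 2, replicate 2 of day 3 or replicate 4 of 3 h, and 19 without replicate 4 of day 2. The 14 genes of day 14 were 2, 7, 4 and 7 without CBNP replicates 1 to 4, 9, 5 and 3 without vehicle replicates 1 to 3, and 9 without CBNP replicate 2 of day 3. There, Ppbp lost its call in 8 of 39 omissions (-1.07 to -0.88). The 10 genes of day 42 were 3 and 22 without CBNP replicates 1 and 3, 6, 4 and 6 without vehicle replicates 1, 2 and 4, 17 without CBNP replicate 1 of day 4, and 19, 6 and 16 without CBNP replicates 1, 2 and 3 of day 3. Bex2 lost its call in 16 of 38 omissions (-1.12 to -0.66), and Ms4a7, Gpnmb and Trem2 without CBNP replicate 1 (1.03, 0.95 and 1.08), Ms4a7 (1.11) and Trem2 (1.27) also without vehicle replicate 2 and Gpnmb without 4 (1.17).

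Vehicle lungs also changed with time. At 3 h, against later vehicle groups, 38 genes were higher and 10 lower (47 in all with slide as a term, 44 in both fits), with the natriuretic peptide clearance receptor Npr3 (1.40 ± 0.17, adjusted p = 2.3e-07), the heat shock proteins Hspa8 (0.83 ± 0.11) and Hsph1 (0.74), and the chemokine Ccl17 (2.11 ± 0.30, 5.18e-06) higher and the cold-inducible RNA-binding protein Cirbp (-1.11 ± 0.13, 6.29e-08) lower. From 2372 genes at an unadjusted p under 0.05, the 48 called were 26 and 31 without vehicle replicates 2 and 5 of 3 h. With Agilent's processed signals 112 genes were called. Among the 8 vehicle groups 323 genes differed (462 with slide as a term, 290 in both fits), led by Fam205a2 (group means 3.04 to 3.43 up to day 5, 1.06 and 0.76 at days 14 and 42, adjusted p = 4.94e-25) and including the clock genes Dbp (1.22 at 3 h, -1.16 at day 1, 2.47 at day 5, 1.7e-13), Nr1d1 and Arntl. The time of day of sampling is not given in the sources used here.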

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

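The tests on the day 2 arrays and on the spread among exposed mice were chosen only after the result was seen, while the counts over other splits of the samples were planned.

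Genes called at day 2 came with 2 exposed arrays of unusually high signal. At day 2 75.1% of probes were well above background in exposed mice against 54.7% in vehicle mice, so a high-signal artefact could account for the calls. Over the 34 vehicle arrays of the 7 times other than day 2, deviations from the group mean gave a slope that accounts for 8.93% of the shift of the 220 higher and 297 lower genes called outside the mitotic list (95% interval -7.73 to 25.6; r = 0.211, permutation p = 0.225, adjusted p = 0.341; rho = -0.124, p = 0.485, adjusted p = 0.485; r = -0.0398 without the 2 farthest arrays, with a share of -1.31%) and for -9.54% of the mitotic shift (-33.7 to 14.7; r = -0.157, p = 0.341, adjusted p = 0.341; rho = -0.258, p = 0.142, adjusted p = 0.284; r = -0.138 without the 2 farthest). A first version of this test pooled the slope over vehicle arrays, and its values are not given here. Over these vehicle arrays the scores thus moved little with signal. But only vehicle replicate 3 of day 5 (87.55%) came near the signal of the 2 exposed arrays, with the next highest at 68.38%. The slope therefore rests on 1 array or on extrapolation, and it does not decide whether high signal gave either shift. An exposed mouse with ordinary signal (replicate 1, 55.38%) had a score over the non-mitotic genes of -4.27 against -5.02 to -4.61 in vehicle mice and a mitotic score of -2.86, inside the vehicle range of -3.21 to -2.18. Replicate 3 (64.75%, vehicle arrays of day 2 up to 62.35%) scored -3.37 and -2.17, above all vehicle mice of that day, though barely so in the mitotic score. The high-signal replicates 2 and 4 scored -2.38 and -2.67 over the non-mitotic genes and -1.63 and -1.81 in the mitotic score. These values were smaller in size than every vehicle score of that day. A high-signal artefact that weakens ratios would move both scores that way, which was not tested. The non-mitotic genes were chosen by calls that include these mice, so how much 2 or 3 mice set the day 2 result stays open, with a biological difference among the 4 exposed mice untested.

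The response varied among exposed mice of the same time. At 3 h and day 1 the lowest exposed mouse (replicates 1 and 2) had an acute phase score of 0.65 and 0.56, inside the vehicle range, as a swap of labels would give. Its partner would then be a vehicle mouse with a raised score, but the highest vehicle scores were 1.02 and 0.97 against 1.54 and 1.66 in the lowest of the other exposed mice (the smaller gap 4.11 pooled vehicle SDs), which argues against a swap at these times, with the other times left open. The test could have come out the other way: in 20 of 20 trial exchanges of another exposed mouse with a vehicle mouse at 3 h, and in 14 of 15 at day 1, the list stayed called and no gap remained. A first version of this test took all 6 times with the list called and is not used, because a swap can end that call. Low array signal could account for low scores: over 37 exposed arrays, deviations of the score and of the percentage well above background correlated at r = 0.215 (permutation p = 0.195, adjusted p = 0.338; rho = 0.134, p = 0.429, adjusted p = 0.485; r = 0.193 without the 2 farthest), which neither shows nor excludes a link. The lowest mouse of 3 h had 44.5% of probes well above background, the lowest of its group. That of day 1 had 55.63%, the highest of its group, so low signal did not mark that mouse. Unequal delivery of particles may also have contributed: the pooled SD was 0.34 in exposed and 0.13 in vehicle mice, a ratio of 2.69, but a biological difference in response would give the same ratio, so they cannot be told apart.

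In 47 tests, each of 1 group on 1 measure, for a single mouse far from the others, 6 found one, where chance gives about 1 in 20. Vehicle replicate 3 of day 5 had 87.55% of probes well above background. Vehicle replicate 4 of 3 h stood apart with a p53 score of -0.13. CBNP replicate 1 of 3 h stood apart with a glucocorticoid-responsive score of 2.03. CBNP replicate 5 of day 14 stood apart with a chemokine score of 0.24. CBNP replicate 1 of day 42 stood apart with a neutrophil chemoattractant score of 0.13. CBNP replicate 5 of day 4 stood apart with a skeletal muscle score of 5.28.

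The effect of CBNP differed between times in 1315 genes by the interaction test. Aryl hydrocarbon receptor targets had a mean effect of 0.25 at 3 h and -0.24 at day 1, a difference of -0.49 (exact permutation within each arm, p = 6.3e-05, adjusted p = 0.0154). The list held 6 measured genes. Of these 2 times camera called it only at day 1, with the preset correlation. Its member with the smallest p at day 1, Ahrr, was well above background on 0 arrays of either arm. Among 21345 probes without a gene symbol, left out of the report's comparisons, limma called 239 at 3 h (169 higher, 70 lower), 5 at day 1 (4 and 1), 291 at day 2 (178 and 113), 4 at day 14 (4 and 0) and 3 at day 42 (3 and 0). These probes were fitted and adjusted together with the named genes.

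The same arrays were put into up to 100 splits with groups of the same sizes, the real one included. Only the real split reached the real count at 3 h (557 genes, highest other 552), day 1 (47, highest other 33), day 2 (537, 473), day 14 (67, 20) and day 42 (59, 58). The same held for the interaction (1315, 204), the vehicle groups (323, 13) and vehicle at 3 h (48, 15). This argues against chance for these counts, with no adjustment over the results. The margins at 3 h and day 42 were narrow, but against splits that kept most of the real grouping (below). For early, day 14 and day 42 minus middle, 2, 4 and 2 splits reached the real 31, 14 and 10 genes. Other splits there called up to 199, 133 and 239 genes, so chance was not excluded for these differences. The highest other splits at 3 h and days 1, 2 and 14 exchanged 1 mouse of each arm. In order, these were CBNP replicate 1 with vehicle replicate 2, CBNP 2 with vehicle 3, CBNP 1 with vehicle 5 and CBNP 5 with vehicle 4. That of day 42 was the real split with the names of the arms reversed and CBNP replicate 3 placed with the vehicle mice. Chance was not excluded for day 3 (10 splits reached 3 genes, highest other 54). All splits used the fit without slide. With slide as a fixed term 23 genes were called at day 3, and that fit was not split. At days 4 and 5, with 0 genes called, every split reaches the real count, so this test decides nothing there (highest other 156 and 2). Why some splits called several times the real count, at days 3 and 4 and in the differences from the middle days, was not tested.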

How the results depend on the processing

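The alternatives without the 3 high-signal arrays, without slides 1 and 2, with the percentage of probes above background as a covariate and with unnamed probes tested too were chosen only after the result was seen, and the other alternatives were planned.

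Of 227 named gene results, 170 kept their direction and call with Agilent's processed signals, 181 from Cy5 alone, 206 with the series matrix values, 221 with no filter, 217 of 217 with a filter of 38 arrays, 218 with the mean of probes, 226 with slide as a random block, slide as a fixed term or scan day as a fixed term, 223 with trended and robust variance, 172 without the 3 high-signal arrays, 192 without slides 1 and 2, 188 with the percentage covariate, 204 with unnamed probes and 111 of 186 with only the 2 groups. Of 118 called lists 97 to 117 kept theirs under these, except that lists were not run for the last 2 settings, and 13 kept it with an estimated correlation. Scaling intensities between arrays leaves ratios as they are, so its identical results say nothing about stability. Results whose gene failed the filter of 38 arrays were left out of its 217, so that share does not cover the genes nearest background. Low signal over background limits what can be said of genes near background.

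The values that moved by more than 1.5 times or turned direction follow, and the cause was not tested except where fewer arrays, more tests or no fold minimum set it. Agilent's processed signals gave 836 genes at 3 h, 1171 at day 2, 0 at day 3, 7 for day 14 and 1 for day 42 against the middle days, 563 among vehicle groups, 112 for vehicle at 3 h, and ciliated cell markers at day 5 at 0.08, reversed. Cy5 alone gave 1490 genes at day 2, 5 at day 5, 3082 for the interaction, 224 for early and 7 for day 14 against the middle days, and reversed Gpr182 (0.49), Slc35g2 (0.15), Fcgbp (0.08) and Esam (0.16) at day 2. The filter of 38 arrays gave 6 at day 3. Slide as a random block gave 20 at day 3, 90 at day 42, 2998 for the interaction, 58 for early and 18 for day 42 against the middle days, 514 among vehicle groups and 1 with 2 phases. Slide as a fixed term gave 23, 3107 and 56 for day 3, the interaction and early against the middle days, and scan day gave 14, 2556 and 48, with 505 among vehicle groups and 1 with 2 phases. Without the 3 high-signal arrays there were 8 at day 2, 7 at day 3, 583 for the interaction and 9 for early against the middle days. Without slides 1 and 2 there were 12 at day 1, 1067 at day 2, 0 at day 3, 2687 for the interaction, 142, 5 and 21 for early, day 14 and day 42 against the middle days, 75 for vehicle at 3 h and 4 with 2 phases. The percentage covariate gave 5 for early against the middle days. Unnamed probes too gave 822 at day 2, 1977 for the interaction and 8 for day 14 against the middle days. Only the 2 groups, with the variance estimated from their own mice, gave 11 at day 1, 120 at day 2, 0 at day 3 and 106 at day 14. No fold minimum gave 1885 at 3 h, 2102 at day 2, 5 at day 3, 103 at day 14, 93 for early against the middle days and 433 for vehicle at 3 h.

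Leaving out each array in turn gave 459 to 790 genes at 3 h, 24 to 62 at day 1, 186 to 998 at day 2, 0 to 84 at day 3, 0 to 1 at day 4, 0 to 0 at day 5, 40 to 78 at day 14, 26 to 77 at day 42, 846 to 2048 for the interaction, 19 to 83 for early, 2 to 21 for day 14 and 3 to 22 for day 42 against the middle days, 236 to 335 among vehicle groups and 26 to 70 for vehicle at 3 h. It reversed the adipocyte list at day 14 (-0.59 to 0.62) and neutrophil markers at day 4 (-0.10 to 0.34), and the complement mean at day 1 turned sign as well (-0.08 to 0.08), as it did without slides 1 and 2 (-0.11).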

Other observations

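The overlap of early and late genes and the step among mice of days 14 and 42 were noticed in these data, and all of their tests were chosen only after the result was seen.

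Some genes were called higher both early and late, most of them without a call at days 3 to 5. Of 669 genes higher at 3 h, day 1 or day 2 and 79 higher at day 14 or 42, 30 were in both sets (2.9 expected if independent), 3 of them also called at day 3 (Lcn2, Ly6f and Noxo1). They included Ch25h, which makes 25-hydroxycholesterol (log2 2.00 at 3 h, 0.25 to 0.73 at days 3 to 5 and 1.47 at day 14), the chemokine Ccl9 (0.89 at day 2, 0.23 to 0.51 at days 3 to 5 and 1.51 at day 42), the neutrophil chemokine receptor Cxcr1 (0.77 at day 2, 0.51 to 0.73 at days 3 to 5, so with little dip, and 1.33 at day 42), the signalling brake Rgs1 (1.08 at 3 h, -0.05 to 0.25 at days 3 to 5 and 1.08 at day 14) and AA467197, known as Nmes1 (1.25 at 3 h, -0.03 to 0.85 at days 3 to 5 and 2.10 at day 42). Ly6i, Cxcl1, Cxcl5, Saa3, Orm2, Serpina3f and C3 belonged to the set as well. A missing call at day 3 is not a lower effect. Ly6i was at 1.59 at day 3 (1.48 at day 2), Ctsk at 0.99 (0.88) and Gpnmb at 0.96 (0.88). Others, such as Cxcl1 (1.00 at day 3, 3.19 at 3 h and 1.47 at day 2), were lower by then. At days 4 and 5 Ly6i was at 0.52 and 0.16, Ctsk at 0.17 and -0.09, and Gpnmb at 0.32 and 0.31. Of 429 genes lower early and 12 lower late, 5 were in both (0.283 expected): Asgr1, Cst8, Ppbp, Prickle1 and Tnxb. These genes were chosen after their values were seen, and the dip between the phases was not itself called by both contrasts for any of them (the exceptions were Cxcl5 with slide as a random block or scan day as a term, and Cxcl5, Gdf15, Lcn2 and Serpina3f without slides 1 and 2).

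Some genes stepped between day 5 and day 14 in both arms. Set on vehicle arrays, 9 genes moved by at least 1 log2 unit, among them Fam205a2 (-2.35), Gm3893 (-2.30), Lrmda, which takes part in pigment cell development (-1.38), Tmem254a (-1.15), the complement inhibitor Cd59a (1.31) and the kinase subunit Camk2b (1.79). In exposed arrays 8 of the 9 moved the same way, Cyp26b1 being the exception (0.82 against -1.85), and for 5 the 57 early and 19 late mice of both arms did not overlap. Within slides the median difference was 97.7% of the pooled one, which argues against slide as the source, and the median move from day 14 to day 42 was -1.68% of the step, which argues against gradual ageing. Mice of another stock with inherited differences are a candidate explanation: 1 pair of these genes, Gm3893 and Fam205a2, lay within 5 measured genes of each other (12 of 1000 random sets had as many). By the rule first written this read as a fit, and a minimum of 2 pairs was added after the result was seen, since 1 pair decides nothing. The labels give no stock per time, so this stays open.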
